A study of Mus musculus with 6 samples.

How the data were processed

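Bone marrow cells of Lepr-Cre;LSL-tdTomato mice were sorted for tdTomato, per the labels' protocols, and ATAC-seq libraries were made with an Omni protocol, in which nuclei are washed to lower the share of mitochondrial DNA. The series holds 3 libraries of mice given PBS and 3 of mice given DOX, and groups and replicate numbers were taken from the sample titles. Whether each library came from a single mouse or a pool is not given in the sources used here, so p-values measure the spread between these libraries.

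The authors deposited a list of peaks for each library, with build mm10 per the submitters' processing notes. These notes name FastQC 0.11.5, MultiQC 1.7, Trim Galore 0.6.6, Bowtie2 2.4.5, Picard 2.10.9, MACS2 2.2.7.1 and DiffBind 3.16.0, among others, with no role or order; no read counts and no comparison made by the authors were used here. The settings of the peak caller, the shift of reads for the Tn5 cut and the filters on reads are not given in the sources used here. Each deposited peak has a start, an end, a fold enrichment, a −log10 p, a −log10 q and a score. All are from the authors' peak caller and are not scaled between libraries. The fold enrichment is the ratio of the pileup at the summit plus 1 to the background plus 1. The score was 10 times the −log10 q in at least 99.7% of deposited peaks, and a last column gives the summit as another kind of value, its position in bp from the start. These are the authors' values for single peaks. Here they served only to rank, filter or describe peaks within their own list, and to solve for depth. No interval was listed more than once. Analyses used chromosomes 1 to 19 and X, which left out 13 to 19 peaks per library on chromosome Y and no other counted peak.

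Depth was recovered from the lists. The fold and the −log10 p of a peak fix its pileup and its background under the Poisson model of MACS2. The 4022 to 4167 peaks per library used to solve it, with a −log10 p under 200, gave in each library a single background, equal to within 1% in 100% of them, so that the caller had used a constant background and not a local one. With that background 100% of pileups were whole numbers to within 0.05. The background is the mean number of fragments per position. It is proportional to the reads used only if the fragment length is the same in all libraries, which is not given. The background was 1.27, 1.10 and 0.558 for PBS replicates 1, 2 and 3 and 1.72, 1.67 and 2.22 for DOX replicates 1, 2 and 3. All DOX libraries were thus deeper than all PBS libraries by this measure. The lowest pileup that was listed was 5 to 7 in PBS and 8 to 9 in DOX. The absence of a peak says that a region was below the threshold of that library, not that it was closed. Pileups at summits are known only where a library has a peak, so no count model was fitted.

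To keep list length from setting the results, each library's peaks were ranked by −log10 p and the strongest 65462 kept, the number of peaks of the shortest list. The weakest kept peak had a pileup of 14 to 16 in PBS replicates 1 and 2, 5 in PBS replicate 3 and 20 to 28 in DOX. Ranking does not equalise width: the median width of the kept peaks was 439, 476 and 328 bp in PBS and 505, 516 and 542 bp in DOX. Peaks of all libraries that overlapped were merged into union regions, and a library held a region if its peaks overlapped it by at least 1 bp. Peaks per union region were most in the shallowest library, PBS replicate 3, and fewer in each DOX than in each PBS library, but within groups they did not follow depth throughout: 65462 peaks stood for 62452, 63320 and 59189 union regions in PBS and for 63758, 64120 and 64374 in DOX.

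Genes and coordinates came from a RefSeq gene table of assembly GRCm38.p6, the assembly that mm10 displays, with 21631 protein-coding genes. It gives the span of each gene without its strand, exons or transcripts. The analyses planned on transcription start sites therefore used gene spans: a summit within 1 kb of either end of a gene counted as at a gene end, other summits as inside or outside a gene, and each peak went to the protein-coding gene with the nearest span within 100 kb of its summit, which assigned 90.9% to 91.5% of peaks. A gene end is thus a promoter or the far end of a gene, and intron, exon and UTR were not told apart. The planned motif shares needed a genome sequence and were not analysed here. The 24 gene lists hold 678 symbols, of which 672 matched the table.

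Per library, peaks, covered length, shares of gene ends and genes with an open end were compared with two-sided exact permutation tests, which cannot give a p under 0.10 with 3 against 3. Similarity was the base-pair Jaccard index, set against the 10 splits of the libraries into 3 and 3. Regions and gene ends with a peak in all libraries of a group and none of the other were counted and set against the same splits. Peaks per gene were tested with limma 3.58.1 on log2(peaks + 0.5), with trend and robust moderation, over genes with a mean of at least 2 peaks, at a Benjamini-Hochberg adjusted p of 0.05. A fold change is on this scale, which understates changes of small numbers. Lists were tested with camera of limma, two-sided, with an inter-gene correlation preset at 0.01 and again estimated, adjusted over the 24 lists. Regions near list members were set against 10000 random lists matched on the number of regions. Other tools were R 4.3.3, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

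The groups, the tests between them, the other splits for similarity and regions, the gene lists, the naming rule and most alternatives were fixed before the data were examined. Named for peaks per gene were up to 12 called genes per direction with no overlap of groups, by size of the log2 fold change (ties by p, then symbol); for the MSPC, osteoblast, adipocyte, p53 and senescence lists, and for any list that passed, the 4 members with the largest absolute log2 fold change; for gene ends up to 10 genes and for regions 5 regions per direction, by median −log10 p. Predicted genes were skipped in the lists of genes, and 1 gene that the rule names is not reported here. Other genes with regions near list members were named after their values were seen. Alternatives were the deposited lists, lists of the strongest 32731 peaks, a −log10 q of at least 5, coverage of at least 50% of a region, a window of 2.5 kb, peaks in the gene span extended by 10 kb, no filter, 1 added in place of 0.5, a block for replicate number, and each library left out. Added after the data were seen were peaks at least 20 times the background, 5 libraries of equal length, union regions counted in place of peaks, summits in the gene end window, random lists and 2 other estimates of the spread. The tests of other splits for gene ends and called genes, of depth as an explanation, of PBS replicate 3 alone and of identical peak numbers were also added then. The bound on regions over the other splits was written then too.

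The scripts were tested on simulated data. All 200, 100 and 3000 planted regions of the second 3 lists, the first 3 lists and all 6 lists were recovered, and a background of 1.37 was solved as 1.37. In simulated peak numbers for the 8784 genes, limma recovered 31 of 50 genes raised 2-fold, 9 of 50 raised 1.5-fold, 4 of 50 lowered to 0.667 and 14 of 50 lowered to 0.5 of their number, with 1 call among 7923 unchanged genes. Small shifts in peak number could therefore be missed, and a change in how open a region was, without loss or gain of a peak, was not measured. The simulated numbers were not matched to the real ones on how many genes had identical numbers within groups. The changed genes were drawn only from genes with a mean of at least 4 peaks, so recovery among genes with fewer was not measured. In the real libraries the splits that mix treatments called 34 to 61 genes. The 1 call among simulated unchanged genes is thus no estimate of false calls in the real data.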

Results

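Open chromatin was measured in mesenchymal stem and progenitor cells (MSPCs) of mouse bone marrow 8 weeks after cyclic doxorubicin. Doxorubicin (DOX) is an anthracycline chemotherapy drug that poisons topoisomerase II and breaks DNA. The mice carried Lepr-Cre and a Cre-dependent tdTomato reporter, so that cells of the leptin receptor lineage, the stromal cells that surround marrow sinusoids and feed blood stem cells, fluoresced red and could be sorted. Female mice that were 8 to 10 weeks old at treatment had received 4 intravenous injections of 5 mg/kg DOX or of phosphate-buffered saline (PBS) at intervals of 1 week. Each group held 3 libraries, which the titles call biological replicates; the number of mice behind each library is not given in the sources used here. The assay was ATAC-seq, in which the transposase Tn5 cuts and tags accessible DNA, so that a peak marks a stretch of open chromatin. The measurements are 6 lists of peaks, each called in a single library, with mm10 coordinates. The comparison asks what the chemotherapy had left in the chromatin of these cells 8 weeks later.

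Gene ends of MSPC genes were mostly open in both groups. Of 30 genes for MSPC identity and niche factors, 28 to 29 had a peak at a gene end in every library, among them Cxcl12, the chemokine that holds blood stem cells in the marrow. All 35 cell cycle genes and 25 to 26 of 26 genes for AP-1 and other immediate early factors also had such a peak in each library. Over all 21631 protein-coding genes the number was 12684 to 12983, and no test of enrichment was run. Of markers of other marrow cells, 8 of 20 B cell genes, 7 to 9 of 27 myeloid genes and 8 to 9 of 25 erythroid and megakaryocyte genes had one. So did 5 to 6 of 22 T and NK cell genes and 12 to 14 of 30 endothelial genes. The ranges are over the 6 libraries of both groups. Among the B cell markers, Ebf1 is also a factor of the MSPC list.

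More peaks were listed after DOX than after PBS. The PBS libraries held 88348, 89264 and 65462 peaks on chromosomes 1 to 19 and X, with a mean of 81025 ± 13485 (SD, n = 3). The DOX libraries held 91026, 91060 and 100642, with a mean of 94243 ± 5542 (SD, n = 3). Every DOX library lay above every PBS library, with p = 0.10 in a two-sided exact permutation test, the smallest p that 3 against 3 allows. The difference of 13218 peaks was 5437 without PBS replicate 3. Peaks covered 39.7 ± 8.62 Mb in PBS and 51.9 ± 2.97 Mb in DOX (SD, n = 3 each; p = 0.10, exact permutation test). The difference in covered length was 12.2 Mb, and 7.34 Mb without PBS replicate 3. The median peak was 343 ± 18.7 bp wide in PBS and 383 ± 5.51 bp in DOX. The DOX libraries were also deeper in fragments per position, though totals of sequenced reads were not available. The background pileup solved from the peak scores was 1.27, 1.10 and 0.558 fragments per position in the PBS libraries and 1.72, 1.67 and 2.22 in the DOX libraries. Among peaks at least 20 times as high as this background the order of the means was the other way, 48980 ± 2251 in PBS and 48469 ± 1286 in DOX (SD, n = 3 each; p = 0.90, exact permutation test). That threshold was chosen after the data were seen. The comparisons below used lists of equal length, as fixed before the data were seen: the 65462 strongest peaks of each library, the length of the list of PBS replicate 3, unless other lists are named.

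**Figure D1:**
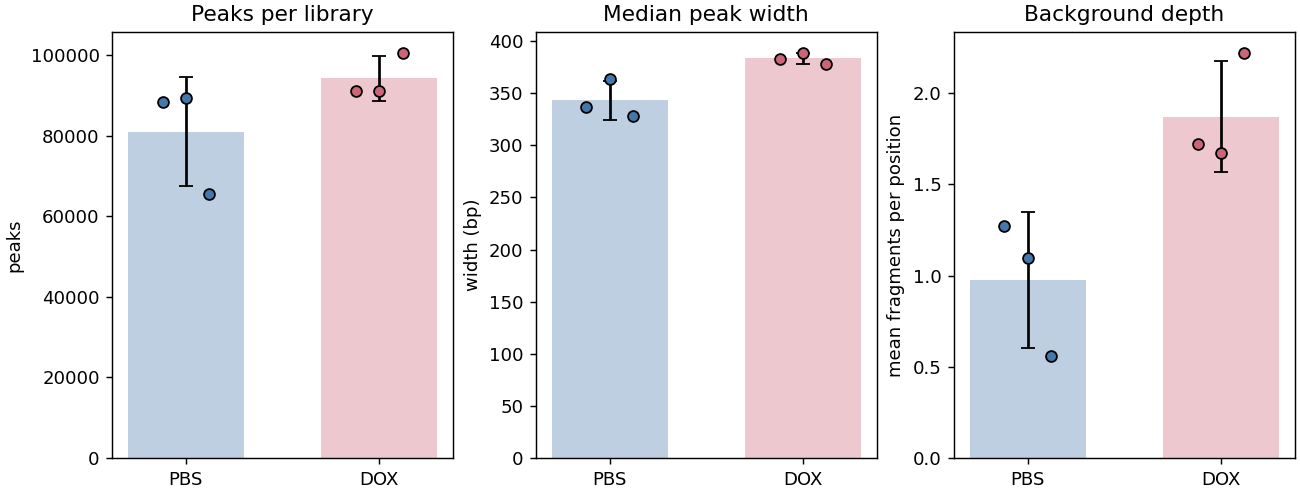
Peaks per library, median peak width in bp and background depth in mean fragments per position, for the 3 PBS and the 3 DOX libraries. Points are libraries, bars the group means and error bars the SD; the background depth of the DOX libraries, 1.67 to 2.22, lies above that of the PBS libraries, 0.558 to 1.27.

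The places of the peaks in the genome differed little between the groups. Summits within 1 kb of either end of a protein-coding gene made up 19.6% ± 0.863 of peaks in PBS and 18.9% ± 0.0145 in DOX (SD, n = 3 each; p = 0.10, exact permutation test). Summits elsewhere inside genes made up 43.2% ± 0.194 and 43.4% ± 0.126 (p = 0.30, exact permutation test), and those outside genes 37.2% ± 0.966 and 37.7% ± 0.113 (p = 0.90, exact permutation test). The difference at gene ends was -0.64 percentage points, and -0.147 without PBS replicate 3.

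Libraries of mice given DOX resembled each other closely. The base-pair Jaccard index is the shared length of 2 peak sets over their joint length. It had a mean of 0.802 (range 0.795 to 0.807, 3 pairs) within DOX, 0.698 (0.651 to 0.765, 3 pairs) within PBS and 0.707 (0.592 to 0.773, 9 pairs) between the groups. Mean similarity within groups exceeded that between groups by 0.043, the largest difference among the 10 ways to split the 6 libraries into 3 and 3, so that p = 0.10 in this exact permutation test, the smallest it allows. The excess ranged from 0.0105 without DOX replicate 3 to 0.0938 without PBS replicate 2. With the index taken over union regions in place of base pairs it was 0.015. There PBS replicates 1 and 2 had 0.833 with each other and 0.824 to 0.838 with DOX libraries. Pairs with PBS replicate 3, the shallowest library, held the lowest values: 0.651 and 0.678 within PBS and 0.592 to 0.625 with DOX libraries.

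Regions that were listed after only 1 of the treatments were more numerous for DOX. Of 78613 regions made by merging the peaks of all libraries, 49098 (62.5%) had a peak in all 6 libraries, 623 had a peak in all 3 DOX libraries and in no PBS library, and 238 the opposite. In the equal-length lists no other set of 3 libraries reached the DOX count; the highest other set had 286 regions and the median of the sets that mix treatments was 191.5. The PBS count lay within the range of those mixed sets, 4 of which had more regions. With peaks at least 20 times the background, a setting chosen after the data were seen, the DOX and PBS counts were 361 and 203, and 1 mixed set, of PBS replicate 2 and DOX replicates 2 and 3, had more than either (375). The regions of both directions lay mostly away from gene ends: 52 of the 623 DOX regions (8.35%) and 14 of the 238 PBS regions (5.88%) were at a gene end, against 22.9% of the regions shared by all 6 libraries. The DOX and PBS shares gave p = 0.254 in a two-sided Fisher's exact test over regions, which are not replicates. Most were differences of rank: 530 of the 623 DOX regions appeared in the full deposited list of at least 1 PBS library and 93 in none, while 236 of the 238 PBS regions appeared in that of at least 1 DOX library. These shares cannot be compared between the directions, since list length bears on them. The deposited list of PBS replicate 3 is its equal-length list and could hold no DOX region. All deposited DOX lists were longer than all PBS lists. Weaker peaks lay less often at gene ends: the mean share in the DOX libraries was 18.9% in equal-length and 15.4% in deposited lists. Shared regions of similar strength were not compared, so the low shares cannot be read as particular to regions listed after 1 treatment. The deposited lists gave 2151 DOX and 43 PBS regions. Without PBS replicate 3 the counts were 955 and 681, and with any other library left out 1025 to 1452 and 380 to 610, since fewer libraries then have to be empty or filled. The DOX and PBS counts then also differ in how many libraries must be filled and empty.

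**Figure D2:**
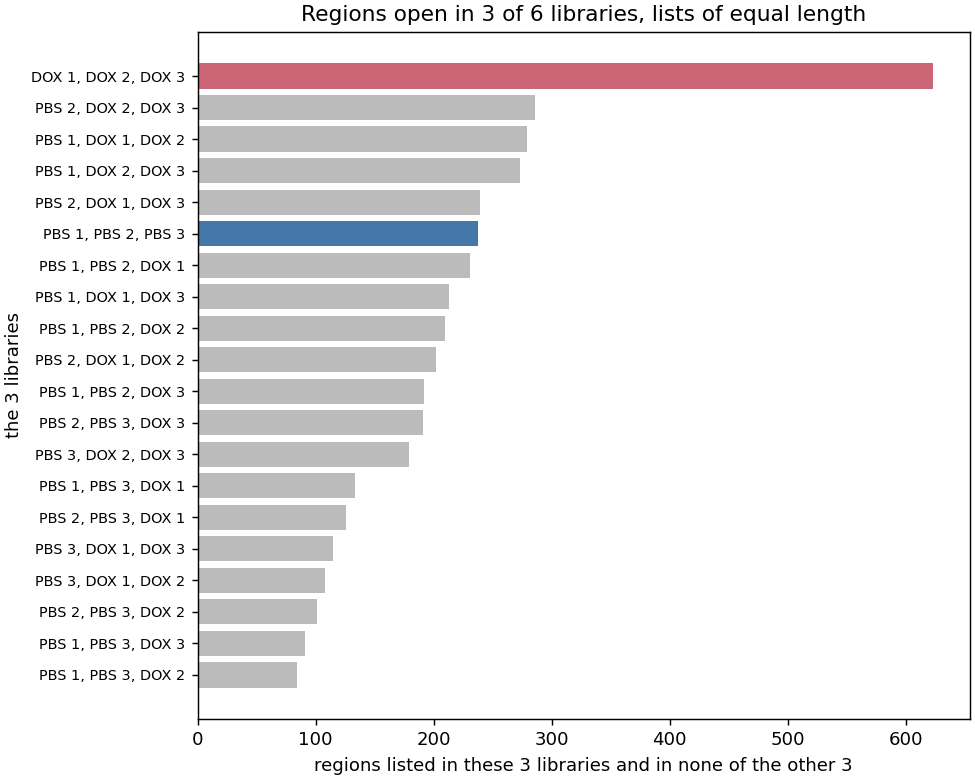
Number of regions with a peak in exactly the 3 libraries named on the left, for each of the 20 sets of 3 libraries, from lists of equal length. The DOX set (red) has 623 regions, the PBS set (blue) 238 and the highest mixed set (grey) 286.

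The strongest DOX regions lay at, in or near Eps8l1, Npr3, Pkhd1, Slc41a3 and Lhx2. The first by median −log10 p was at a gene end of Eps8l1, which encodes a relative of the actin regulator EPS8 (chromosome 7, 4460552 to 4461086). The next lay inside Npr3, the clearance receptor of natriuretic peptides (chromosome 15, 11851852 to 11852214), inside Pkhd1, the fibrocystin gene (chromosome 1, 20414725 to 20415143), and inside Slc41a3 (chromosome 6, 90607206 to 90607535). The fifth was 9644 bp from Lhx2, a LIM homeodomain factor (chromosome 2, 38379142 to 38379500). Of these only the Slc41a3 region was missing from the full lists of all 3 PBS libraries. The strongest PBS region lay inside Ncoa1, a nuclear receptor coactivator (chromosome 12, 4417716 to 4417977). The next had no protein-coding gene within 100 kb (chromosome 13, 25701838 to 25702535). It was followed by regions 41993 bp from Adpgk (chromosome 9, 59249447 to 59249769) and 30647 bp from Ap4e1 (chromosome 2, 126977917 to 126978191). Level with the latter was another without a protein-coding gene within 100 kb (chromosome 4, 31203288 to 31203668). All 5 were in the full lists of all 3 DOX libraries, which were longer than those of the PBS libraries.

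Of the MSPC list 4 genes had regions listed in DOX only and 2 in PBS only, and only Cxcl12 had both kinds. At Cxcl12 (chromosome 6, 117168535 to 117181368), 2 regions were listed in the DOX libraries only. They lay inside the gene (117172117 to 117172320) and at a distance of 24475 bp (117205628 to 117206304). The peaks of the distant region were 12.8, 14.3 and 14.4 times the background in DOX replicates 1, 2 and 3. The lowest kept peaks of these libraries were 11.6, 12.6 and 12.6 times the background. A single region was listed in the PBS libraries only, 5842 bp from the gene (117186310 to 117187386). Ebf1, a factor of MSPCs and of B cells, had 2 DOX regions inside the gene, and Fstl1 also had 2. Prrx1, a factor of limb mesenchyme, had 1 DOX region at a distance of 13690 bp that no PBS library listed at all, and Igfbp5 had 1 PBS region. The MSPC list held 7 DOX regions, against 4.92 expected in random gene lists with as many regions (p = 0.421, two-sided permutation test with 10000 random lists). The adipocyte list held 4, near Acsl1, Cidec, Zfp423 and Gpd1, against 2.27 (p = 0.371, same permutation test). In no list of the 24 did the number of regions of either kind pass Benjamini-Hochberg adjustment (adjusted p = 1 in each).

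**Figure D3:**
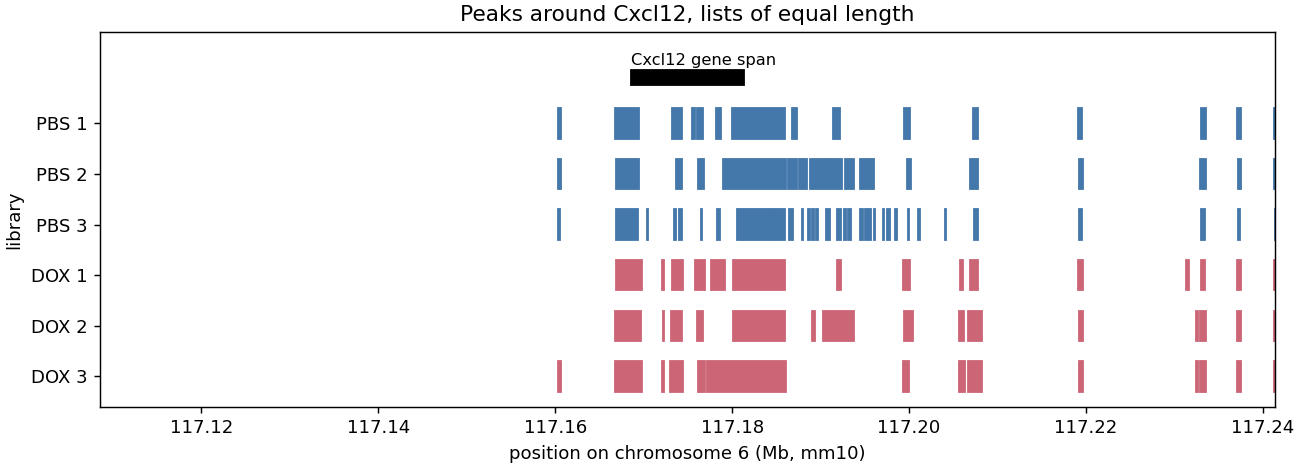
Peaks of the equal-length lists around Cxcl12 on chromosome 6 (position in Mb, mm10), 1 row per library, blue for PBS and red for DOX; the black bar is the span of the gene from 117168535 to 117181368. The DOX libraries share narrow peaks inside the gene and wider ones at 24475 bp from it that the equal-length PBS lists lack. PBS replicate 3 shows many narrow neighbouring peaks to the right of the gene where other libraries list fewer or wider ones.

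Gene ends repeated this pattern on a small scale. A peak touched the 1 kb around an end of 12806, 12821 and 12684 protein-coding genes in PBS and of 12909, 12951 and 12983 in DOX. The means were 12770 ± 75.1 and 12948 ± 37.1 (SD, n = 3 each; p = 0.10, exact permutation test). The ends of 39 genes were open in all 3 DOX libraries and no PBS library, and those of 5 genes in the opposite way. Sets of 3 libraries that mix treatments had 2 to 14 such genes, so the PBS count lay within their range. Among the 10 DOX genes with the strongest peaks were Nudt16, Dnajc1, Klf15, a factor of adipocyte differentiation, Lmbrd1, Nudcd3, Pex2, a peroxisome assembly gene, and Zan. The peaks of these 7 reached the window without having their summit in it. The other 3 were Eps8l1, Siglec1, a macrophage sialic acid receptor, and Blk, a kinase of B cells, and these were also DOX genes when the summit had to lie in the window. The 5 PBS genes were Tlr12, Crybb3, Pou4f1, Gkn3 and Rhbdl2, and all 5 met the summit rule. With a window of 2.5 kb the counts were 26 and 5 genes, which kept 17 of the 39 DOX genes and 2 of the 5 PBS genes: of the named ones Blk, Crybb3 and Rhbdl2. In the deposited lists the counts were 77 and 0 genes, and Eps8l1, Siglec1 and the 5 PBS genes were lost. With each library left out the counts were 48 to 80 and 10 to 18 genes. With the summit rule the counts were 28 and 21 genes, and the number of genes with an open end was 12322 ± 32.3 in PBS and 12351 ± 15.9 in DOX (SD, n = 3 each; p = 0.30, exact permutation test).

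The number of peaks assigned to a gene differed between the treatments in few genes. Of 8784 genes with a mean of at least 2 peaks, 47 gained and 49 lost peaks in DOX by limma at an adjusted p of 0.05, and 1603 had the same number in all 6 libraries. With union regions counted in place of peaks the balance was different, 75 genes that gained and 24 that lost. In 92 of the 96 called genes the 3 libraries of each group had identical numbers, and in 89 the groups differed by 1 peak. Rgs7bp, which encodes a protein that binds regulators of G protein signalling (chromosome 13, 104945904 to 105054930), had 3 peaks in each PBS library and 6 in each DOX library, a log2 fold change of 0.89. Gtpbp4, a GTPase of ribosome assembly (chromosome 13, 8972070 to 8996116), had 4 in each PBS and 6 in each DOX library. Tmprss9, a transmembrane serine protease (chromosome 10, 80871117 to 80899495), had 1, 1 and 1 in PBS and 3, 3 and 4 in DOX, with a log2 fold change of 1.34 ± 0.12 (SE; limma, adjusted p = 0.0218). Nrde2, a gene of RNA surveillance (chromosome 12, 100125450 to 100160414), had 2, 2 and 2 in PBS and 4, 4 and 5 in DOX, with a log2 fold change of 0.94 ± 0.09 (SE; limma, adjusted p = 0.0364).

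The other genes named by the rule each moved by 1 peak. Those with 2 peaks in each PBS and 3 in each DOX library included Ccl7, a monocyte chemokine (chromosome 11, 82045712 to 82047525), and Alas1, the first enzyme of heme synthesis. Others were the lysosomal enzyme gene Aga, the gamma-secretase gene Aph1c, and Cab39l, Ccdc90b and Dcaf12. Those with 3 in each PBS and 2 in each DOX library included Phgdh, the first enzyme of serine synthesis (chromosome 3, 98313171 to 98339969). Others were the extracellular matrix gene Aebp1, the small GTPase gene Rab10, the chromatin protein gene Hmgb3, and Dhrs1, Eef1akmt4-ece2, Lratd2, Lyrm1, Plekhs1, Pttg1ip, Rcn3 and Rhbdl2. Each of these changed by 0.49 on the log2 scale of peaks plus 0.5, or by -0.49, with a limma adjusted p of 1.02e-08. These values rest on the absence of spread, and all 92 tested genes with constant but different numbers in the groups were called. Raising the spread of each gene to at least the mean of genes with similar numbers left 0 called genes with limma's degrees of freedom. That fit is strict for all genes (137 at an unadjusted p under 0.05, where 439.2 are expected by chance). With the deposited lists scaled to their totals 3 genes were called, none of them among the 96.

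The MSPC list of 30 genes did not move as a group. Its median log2 fold change was -0.04, with 12 members higher and 18 lower in DOX (limma camera, adjusted p = 0.799). The median was 0.01 without PBS replicate 3 and 0.02 with union regions counted. A single member (1 of 30) passed the test both over all genes and adjusted over the list alone. That member was Vcam1, the adhesion molecule that binds blood cells to stroma (chromosome 3, 116110020 to 116129688), which rose from 11, 11 and 11 peaks in PBS to 14, 14 and 15 in DOX. Its log2 fold change was 0.37 ± 0.03 (SE; limma, adjusted p = 0.0196). The call on Vcam1 was lost in 8 of the 16 alternatives. These were the deposited lists, lists of the strongest 32731, the replicate block, no PBS replicate 1, peaks at least 20 times the background, union regions counted, and the pooled and the raised spread (limma, adjusted p from 0.0512 to 1). Its log2 fold change was above 0 in all 16, from 0.12 to 0.61. Cxcl12 had 21, 22 and 38 peaks in PBS and 19, 21 and 16 in DOX, a log2 fold change of -0.48 ± 0.28 (SE; limma, adjusted p = 0.795). Ebf3, which maintains the niche function of MSPCs, had 29, 44 and 72 in PBS and 31, 39 and 35 in DOX. Tnfrsf11b, which encodes the osteoclast inhibitor osteoprotegerin, had 6, 6 and 5 in PBS and 8, 8 and 7 in DOX (log2 fold change 0.41 ± 0.10, SE; limma, adjusted p = 0.448).

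Neither the osteoblast nor the adipocyte list passed the threshold. Of 25 osteoblast genes 5 had more and 18 had fewer peaks in DOX, with a median log2 fold change of -0.05 (limma camera, p = 0.0129, adjusted p = 0.199; unadjusted p = 0.0862 with an estimated correlation). Atf4, a factor of osteoblast maturation, had 2.67 ± 0.577 peaks in PBS and 1.67 ± 0.577 in DOX (SD, n = 3 each), and Zfp36l1, an RNA-binding protein, 14.3 ± 0.577 and 10.7 ± 2.31. Sost, the gene of the bone formation inhibitor sclerostin, had 2.33 ± 0.577 and 1.67 ± 0.577, and Phex, a gene of phosphate balance in bone, 11.3 ± 1.53 and 9.33 ± 1.15. Of 21 adipocyte genes 14 had more and 4 had fewer peaks in DOX, with a median of 0.10 (limma camera, p = 0.0967, adjusted p = 0.773; unadjusted p = 0.143 with an estimated correlation). The lipid carrier gene Fabp4 had 2.33 ± 0.577 peaks in PBS and 3.33 ± 0.577 in DOX, and Acsl1, which activates fatty acids, 5.33 ± 0.577 and 7 ± 1. The lipid droplet gene Plin1 had 2.33 ± 0.577 and 3 ± 1, and Dgat2, which makes triglycerides, 5.33 ± 0.577 and 6.33 ± 0.577. None of the osteoblast or adipocyte members passed limma over all genes or adjusted over the list alone. When union regions were counted in place of peaks the osteoblast median was 0.04 and the adipocyte median 0.10 (limma camera, adjusted p = 0.926 and 0.663). Without PBS replicate 3 they were 0 and 0.05. With the replicate number as a block the osteoblast list passed at the preset correlation, but not at the estimated one.

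The numbers of peaks near genes of the responses that doxorubicin sets off showed no common change 8 weeks later. The 25 tested p53 targets had a median log2 fold change of 0, with 8 higher and 8 lower (limma camera, adjusted p = 0.953), and no member passed limma over all genes or adjusted over the list alone. Btg2, an antiproliferative p53 target, had 10, 10 and 16 peaks in PBS and 8, 8 and 7 in DOX (log2 fold change -0.58 ± 0.22, SE; limma, adjusted p = 0.655). The repair polymerase gene Polk had 2.67 ± 0.577 in PBS and 3.67 ± 0.577 in DOX (SD, n = 3 each). Perp, a gene of p53-dependent death, had 2.33 ± 0.577 and 1.67 ± 1.15, and Phlda3, an inhibitor of Akt, 4 ± 1 and 3 ± 0. The 25 genes of senescence and its secretory phenotype had 11 higher and 11 lower (limma camera, adjusted p = 0.799), and 1 member, Ccl7, passed over all genes and adjusted over the list alone. Cxcl1, a neutrophil chemokine, had 4 ± 1 peaks in PBS and 5 ± 0 in DOX, the adhesion gene Icam1 3.33 ± 2.31 and 2.33 ± 0.577, and Igfbp7, a secreted senescence factor, 18.7 ± 2.31 and 22 ± 1. The 22 DNA repair, 17 cell cycle and 27 oxidative stress genes had adjusted p of 0.951, 0.876 and 0.951 by limma camera, and no member of these 3 lists passed limma over all genes or adjusted over the list alone.

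The largest median shift of a list downward was that of 24 genes for AP-1 and immediate early factors, the first responders to stimuli. It was -0.17, with 7 members higher and 15 lower in DOX (limma camera, p = 0.0166, adjusted p = 0.199; unadjusted p = 0.369 with an estimated correlation), and no member passed limma over all genes or adjusted over the list alone. Without PBS replicate 3 the median was -0.05, and with union regions counted it was 0.

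Of the 24 lists none passed camera after adjustment, and 2, osteoblast and AP-1, had an unadjusted p under 0.05. Among the signalling lists the adjusted p by limma camera was 0.949 for inflammatory and NF-kB genes, 0.951 for interferon response genes, 0.953 for TGF-beta and BMP genes, and 0.799 for both Wnt and Notch genes. It was 0.876 for the chondrocyte list, 0.876 for fibroblast and matrix genes, 0.799 for pericyte and smooth muscle genes and 0.951 for housekeeping genes. The markers of other cells had 0.920 for B cells, 0.799 for myeloid cells, 0.876 for erythroid cells and megakaryocytes, 0.799 for T and NK cells, 0.799 for endothelial cells and 0.856 for Schwann and neural cells. Over all genes and adjusted over the list alone, the inflammatory list held 1 called gene with more peaks, Vcam1, and 1 with fewer, and the Wnt list 1 with fewer. The last pair, named after their values were seen, were the repressor gene Nfil3 and Znrf3, an inhibitor of Wnt receptors, each with 10 peaks in every PBS and 9 in every DOX library.

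**Figure D4:**
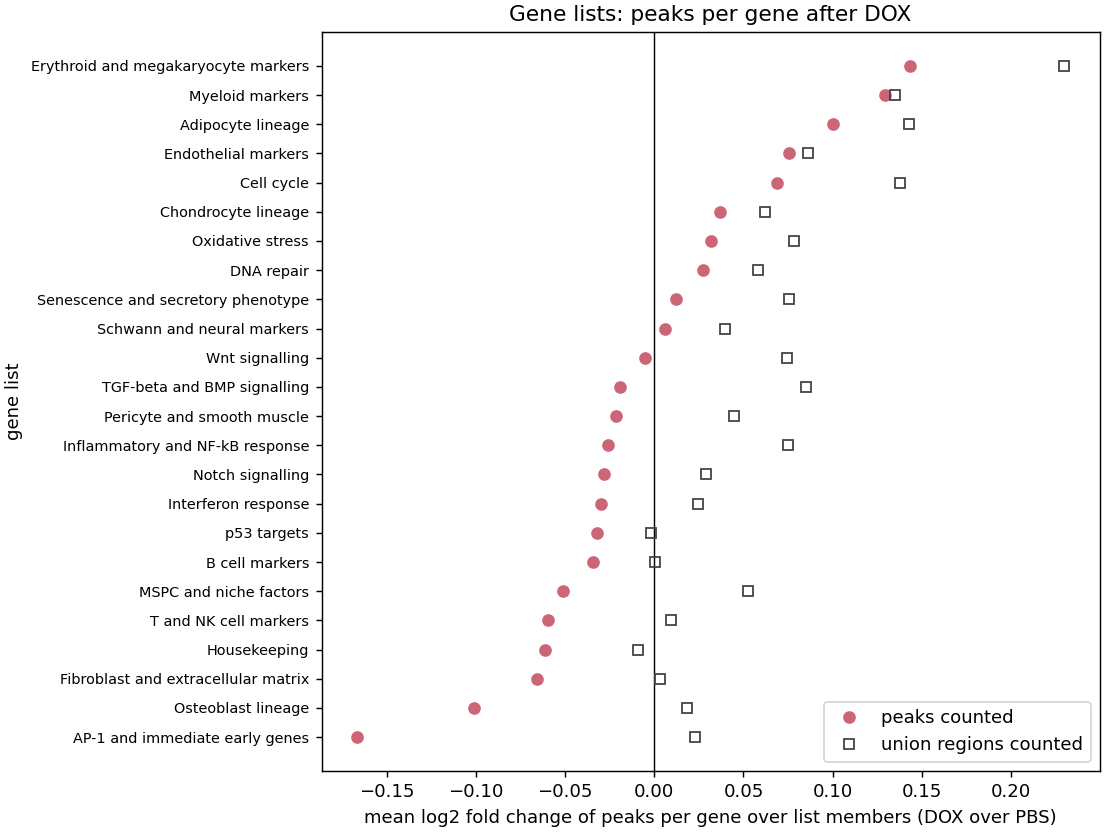
Mean log2 fold change (DOX over PBS) of peaks per gene over the members of each of the 24 lists, with peaks counted (red points) and with union regions counted in place of peaks (open squares). The points run from AP-1 and immediate early genes at -0.17 to erythroid and megakaryocyte markers at 0.14, and no list passed limma camera with either count.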

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

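The settings with 20 times the background, 5 re-equalised libraries, union regions counted, pooled or raised spread, summits in the window and random lists were chosen after the data were seen. Of 150 comparison values under alternatives, 87 counted as kept, those per library by direction alone. Similarity counted as kept if its direction held and it moved by no more than the SD of the index over pairs within groups. That SD is larger than the difference itself, so this rule is lenient too. The cause of changes was not tested, except where named. Covered length, shares at gene ends and inside genes, similarity and the number of genes with an open end kept their direction under all alternatives run on them; similarity within minus between groups ranged from 0.0105 without DOX replicate 3 to 0.0938 without PBS replicate 2. The difference in peaks per library (DOX minus PBS) was -511 with peaks at least 20 times the background. The share outside genes differed by -0.0973 percentage points without PBS replicate 3 and by up to 0.757 without PBS replicate 1. Regions in DOX only and PBS only numbered 2151 and 43 in the deposited lists, 293 and 162 in lists of the strongest 32731, and 2270 and 24 at a −log10 q of at least 5. They numbered 361 and 203 at 20 times the background (where another set of 3 had 375), 1732 and 148 with 50% coverage, and 0 and 0 when the strongest 32731 were set against full lists, which gave 0 in all 10 splits and so says nothing of treatment. With 5 libraries of equal length (88348 peaks) and no PBS replicate 3 they numbered 1626 and 877. With each library left out they ranged from 955 (without PBS replicate 3) to 1452 (without PBS replicate 2) and from 380 (without DOX replicate 2) to 681 (without PBS replicate 3), since fewer libraries then have to be empty or filled. In all settings with 5 libraries the DOX and PBS counts differ in how many libraries must be filled and empty. Gene ends in DOX only and PBS only numbered 77 and 0 in the deposited lists, 26 and 5 with a window of 2.5 kb (17 of the 39 and 2 of the 5 genes kept; 31 in both directions, highest other split 20), 28 and 21 by summit, and 48 to 80 and 10 to 18 with each library left out.

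Genes called with more and with fewer peaks in DOX (limma, adjusted p of 0.05; 47 and 49 as reported) numbered 3 and 0 in the deposited lists scaled to their totals, 74 and 66 in extended gene spans, 112 and 93 with no filter, 40 and 45 in lists of the strongest 32731, 35 and 46 at 20 times the background, and 75 and 24 with union regions counted. Similar counts were not the same genes: of the 96 genes, those tested and still called were 0 of 96 in the deposited lists, 3 of 53 in lists of the strongest 32731, 6 of 85 at 20 times the background, 45 of 80 in extended gene spans and 55 of 95 with union regions counted. With the spread pooled over genes of similar peak number they numbered 83 and 83, of which 4 were among the 96, and with each gene's spread raised to at least that mean 0 and 0 (unadjusted p under 0.05: 73 and 64). With each library left out they ranged from 95 (without DOX replicate 3) to 145 (without PBS replicate 2) and from 71 (without DOX replicate 2) to 138 (without PBS replicate 2), since pairs of libraries more often have identical numbers. With the replicate number as a block they numbered 21 and 18, and 1 list was past the threshold, osteoblast (limma camera, adjusted p = 0.0412; over the other alternatives its adjusted p was above 0.05). With an estimated correlation it did not pass there (limma camera, unadjusted p = 0.190, adjusted p = 0.972). The numbers do not pair the libraries: the deviations of PBS and DOX libraries with the same number correlated by 0.00241, -0.0262 and -0.00628. The lists were run under 14 alternatives, without the pooled and raised spread, and in no other of these did a list pass. In 69 of 336 values under alternatives a list had the other direction. For named genes 642 values under alternatives were computed. In 10 of them the sign changed, and for a called gene this was so for Gtpbp4 (-0.10), Aph1c (-0.0304), Cab39l (-0.0304) and Ccl7 (-0.0304) in the deposited lists and for Dhrs1 (0.12) in extended gene spans. In 123 a call was lost, and in 4, with the pooled spread, one was gained (Cxcl12, Ebf3, Zfp36l1 and Btg2). The motif shares and the windows around transcription start sites were not run, for want of a genome sequence and of strands. Depth limits what a missing peak means, and most of all in PBS replicate 3.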

Other observations

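Tests chosen only after the result was seen were those of other splits for gene ends and called genes, of depth, of PBS replicate 3 alone and of identical peak numbers. The test of other splits for regions was in the design, but its bound was written after the result was seen. The tests of other splits for similarity and of merged peaks at AP-1 genes were written before.

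Regions listed in all DOX libraries and no PBS library lay near members of several lists, in no list beyond matched random lists after adjustment. Among p53 targets there was 1, against 0.911 in random lists (p = 1, two-sided permutation test), in Trp53inp1, a stress-induced gene of autophagy and cell death (chromosome 4, 11166625 to 11166791, inside the gene). Of the 4 of the adipocyte list, against 2.27 in random lists (p = 0.371, same permutation test), 1 was in Zfp423, a factor of preadipocyte commitment (chromosome 8, 87796243 to 87796501, inside the gene). Both regions, and that near Prrx1 (chromosome 1, 163231349 to 163231648), were in the full list of no PBS library. Zfp423 also held a PBS region (chromosome 8, 87859941 to 87860356). A DOX region at a gene end of Lcn2, the iron-binding lipocalin of inflammation (chromosome 2, 32387765 to 32388103), was listed in 1 full PBS list; the inflammatory list held 3 such regions, against 2.135 in random lists. No AP-1 or housekeeping gene had a region of either kind, and the expected numbers of DOX regions in matched random lists were 1.34 and 0.8.

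Fry and Ercc6l2 had 3 DOX regions each and no PBS region, the highest net number of any gene. Libraries held 17, 19 and 18 peaks on chromosome Y in PBS and 13, 15 and 14 in DOX, although the mice were female.

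More regions were listed in DOX only (623) than in PBS only (238), and 861 in both directions, against at most 470 in the other 9 splits. The real split was 1 of 10 with as many regions, and it was also the 1 split with as large a difference in similarity (0.043, highest other 0.0147) and the 1 split with as many gene ends (44, highest other 17); 10 splits are too few for a share under 0.05. PBS replicate 3 alone is argued against as the whole source, since with 5 libraries of equal length the DOX libraries had 1626 regions, 1.8 times the highest other split (904), and the PBS libraries 877. These lists held 88348 peaks, so that 1626 compares with 904 and not with the 623 from lists of 65462, and they leave the depths of the groups apart. In lists of 65462 without PBS replicate 3 the counts were 955 and 681. Their directions differ in how many libraries must be filled and empty, so they cannot be set against 623 and 238. A share of PBS replicate 3 in the excess stays open. Depth cannot be told apart from treatment: the lowest DOX background was 1.32 times the highest PBS background, and equal list length does not undo this. An effect of DOX on the chromatin of these cells stays open beside depth, and it was not tested apart from it.

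Fewer peaks were listed near AP-1 and immediate early genes in DOX, with a median log2 fold change of -0.17 in the equal-length lists. The shift depended on the lists used, and the median was -0.02 in the deposited lists scaled to their totals. A candidate explanation is that neighbouring peaks merge in deeper libraries. Peaks per 100 union regions numbered 104.8, 103.4 and 110.6 in PBS and 102.7, 102.1 and 101.7 in DOX, an order that follows depth between the groups but not between replicates 1 and 2 of either. With union regions counted the median was 0, above the bound of -0.05 set for this explanation, with 9 members higher and 9 lower. That count raised the mean of all genes from 0.0066 to 0.0521, and the list mean, 0.0228, stayed below it (limma camera, adjusted p = 0.900). A smaller effect of DOX at these genes stays open and was not tested.

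The 96 genes called by peaks per gene may come from identical small numbers within groups, since 92 of them had no spread in either group and 89 differed by 1 peak. This and real change cannot be told apart here: a spread taken from other genes bears hardest on genes called for having none. With the spread pooled over genes of similar peak number 4 of them were still called. With a raised spread none was, in a fit with 137 genes at an unadjusted p under 0.05. Without the raised spread limma had 174 to 271 such genes in the splits that mix treatments. Both fits take the spread of the 92 genes from other genes, so neither decides. A bound written earlier counted called genes of any kind, and the pooled fit, with 166, went past its upper limit of 48; it was replaced after that result by a count of shared genes, because the pooled fit calls other genes, such as Cxcl12, whose own spread is large. The real split called 96 genes, the highest other split 61 (1 of 10 splits with as many), and 10 splits are too few for a share under 0.05. Real gains and losses among the 96 stay open.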
